A study of Mus musculus with 69 samples.

How the data were processed

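The labels describe 69 samples, 42 of RNA-seq and 27 of CUT&RUN, from CJ7 mouse ES cells and embryoid bodies. RNA-seq values were read from 3 tables, 1 for DMSO and GSK343 cultures with 12 libraries, 1 for wild-type and EZH2-mutant cultures with 18 and 1 for replated cultures with 11, so 41 libraries in 16 groups were analysed. Library 3 of GSK343 then GSK343 was not analysed here. Groups were assigned from the labels and the column names, before the data were examined, together with the comparisons, tests, gene lists and alternatives.

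The values in these tables are RPKM, which corrects reads for gene length and library size, per the file headers and the names of the deposited tables. STAR 2.5.3, featureCounts 1.6.1, edgeR and HOMER 4.10.3 and the genome build mm10 are named for RNA-seq per the submitters' processing notes, with no role or order given to each. Annotation, filters and use of strand are not given in the sources used here. In the DMSO and GSK343 table and the replating table, RPKM times the deposited gene length sums to 1 M in each library. In the wild-type and mutant table the authors' RPKM carry a further scaling per library, since the same sum, taken with the lengths in the other deposited tables, runs from 0.811 to 2.23 M. That table has 14772 genes, of which 138 had no length in the other tables. Low values are whole multiples of 1 step per library, so reads were recovered by dividing by the step, and 100% of the values were within 0.02 of a whole read. Depth is given on that basis in the report, and 1 read stands for a larger RPKM in the replated libraries, the shallowest at 2.27 M (mega) reads.

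The authors' deposited table of each experiment also holds log2 fold changes and adjusted p-values of the authors' own comparisons, per the file headers, which were counted at an adjusted p of 0.05 and used for nothing else. The deposited PRC2_target call, YES or NO per gene, was used as the authors gave it, and its rule is not given in the sources used here. The authors' group averages, logCPM and unadjusted p-value columns were not used, and 0 per-sample columns were left aside. Peak coordinates are the authors' deposited start and end positions, made with Bowtie2 2.3.4.3 and HOMER 4.10.3 on mm10 among the tools named per the submitters' processing notes. They comprise 4 sets merged over the wild-type stages and 9 Suz12 lists of single libraries.

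Tests were run with limma 3.58.1 in R 4.3.3. RPKM were put on the log2 scale with a pseudocount of 1, genes were kept where RPKM was at least 0.5 in at least as many libraries as the smallest group has, and the groups of a table entered 1 fit (lmFit, contrasts.fit, eBayes with trend). This left 14016 of 14607 genes in the DMSO and GSK343 table, 14180 of 14772 in the wild-type and mutant table and 14367 of 14833 in the replating table. P-values were adjusted with Benjamini-Hochberg within a contrast at a threshold of 0.05. Groups were compared only within a table, except for the Xist levels in the test of feeder share. Differences between effects were tested as interaction contrasts.

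Of 21 gene lists fixed before the data were examined, 19 had at least 3 members tested, and they were tested with limma's camera at a preset correlation between genes of 0.01, adjusted with Benjamini-Hochberg over the lists of a contrast. They are naive and general pluripotency, formative and primed pluripotency, primitive streak and early mesendoderm, visceral and definitive endoderm, cardiac muscle, blood and endothelium, neural, Hox, Polycomb-repressed developmental regulators, trophoblast, germline, imprinted, PRC2 subunits, PRC1 subunits, p53 targets, hypoxia and glycolysis, cell division, feeder fibroblast and mesenchyme, and ribosomal protein genes. The 2-cell-like and mitochondrially encoded lists had no member tested. Imprinted genes share 3 members with the trophoblast list and 1 with the feeder list. Camera with the correlation estimated from the residuals was added after the preset results had been seen, and its adjusted p is printed beside the list calls of the main fits in Results.

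Named genes follow a rule fixed before the data were examined. For each main comparison these are the 5 largest rises and 5 largest falls past the threshold with a group mean of at least 1 RPKM in the higher group and no overlap between groups, without predicted, RIKEN and histone genes. From each list described they are the members with the smallest p, and Ezh2, Eed, Suz12, Ezh1, Pou5f1, Nanog, Sox2, Cdkn2a, T, Gata4, Sox17, Pax6, Hoxb13 and Hoxa9 throughout. Hoxa9 was tested only in replated cells.

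Targets of PRC2 had been planned as genes with a transcription start within 1 kb of a merged H3K27me3 peak. Starts cannot be read from gene spans without strand, so the authors' deposited PRC2_target call took their place, and gene spans within 1 kb of a peak served as an alternative. Both were chosen after the files were seen. Spans came from a RefSeq table, with 15903 of 15924 genes matched. The targets' median was also set beside 10000 random gene lists matched in 20 bins of mean expression. Peak overlaps of at least 1 bp were counted with bedtools 2.31.1, and the 95% intervals are Wilson intervals. Agreement of mutant and GSK343 effects was tested with a one-sided Fisher's exact test over genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with SciPy 1.17.1 for the intervals.

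The replicate numbers 1 to 3 are shared between groups in the labels. They were taken to pair libraries where, with 3 or more pairs, each pair's deviations from the group means correlated above 0.1 across genes. This held for mutant against wild type at day 4 (lowest r 0.290), wild-type day 4 against ES cells (0.151), wild-type day 8 against day 4 (0.222), mutant day 4 against ES cells (0.339) and mutant day 8 against day 4 (0.460). The pairing comes from these correlations and not from the labels.

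The steps were tested on simulated data with 200 changed genes. In the simulated mutant day 8 comparison over 14180 genes, 52% of changes of 1 on the log2 scale and 90% of changes of 2 were called, with 12 false calls. For GSK343 at day 8 over 14016 genes the shares were 58% and 96% with 10 false calls, and for replated GSK343 then DMSO over 14367 genes 1% and 41% with 3 false calls. Camera called the shifted list in each simulation, and 1 of 19 unshifted lists in the mutant simulation and 0 in the others. Simulated genes were drawn independently, so these runs do not test camera, or the counts of calls, where genes correlate.

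The alternatives were a pseudocount of 0.1, no filter, a filter at 2 RPKM, libraries centred on their median, the replicate number as a block, only the groups of the contrast in the fit, eBayes without the trend, leaving out each library in turn, an added minimum of 1 for the absolute log2 fold change in the agreement, and for peaks the longer 50% of the peaks and an overlap of at least 50% of the smaller peak. Added after the data were seen were voom on the recovered reads, the wild-type and mutant table without its second libraries, the comparison of GSK343 then GSK343 with DMSO then GSK343, and replated contrasts without DMSO then DMSO library 1. CUT&RUN samples without a peak file were not analysed here.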

Results

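RNA-seq was done on CJ7 cells, an established mouse embryonic stem (ES) cell line, and on the embryoid bodies, aggregates of differentiating cells, made from them. The series asks what H3K27me3, the repressive histone mark laid down by Polycomb repressive complex 2 (PRC2), does during early differentiation and in cells that have already differentiated. EZH2, the main catalytic subunit of PRC2, was either mutated or inhibited with GSK343. This small molecule was given at 4 µM from 3 days before differentiation, with dimethyl sulfoxide (DMSO) as the vehicle. Libraries came from ES cells on feeder cells (day 0), from embryoid bodies at day 4 and day 8, and from embryoid bodies replated in ES cell medium for 5 days (day 14). In replated groups the first-named treatment was given during embryoid body differentiation and the second after replating. The 41 libraries with values formed 16 groups. There were 2 libraries in each DMSO or GSK343 group, 3 in each wild-type or mutant group, 3 in each of 3 replated groups and 2 in GSK343 then GSK343.

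Reads recovered from the values ran from 5.01 to 22.0 M (mega) per library for DMSO and GSK343. GSK343 ES cell library 2 was the shallowest there, and the others held at least 16.4 M. They ran from 7.17 to 28.5 M for wild type and mutant and from 2.27 to 8.34 M for replated cells. The ribosomal RNA gene Rn45s took 6.38% to 11.5% of reads in the DMSO and GSK343 libraries and 8.66% to 34.0% in replated libraries. In wild-type and mutant libraries it took 4.08% to 57.9%, and the highest share was in wild-type day 4 library 2. Values are group means ± SD in RPKM. Fold changes are differences of log2(RPKM + 1) with their standard error (SE), which understate changes of genes at low values. Adjusted p-values are from limma with Benjamini-Hochberg adjustment. The p-values measure spread between these libraries, and the labels do not say whether replicates were separate cultures.

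Ezh2 was measured first, because it was the gene targeted in the mutant line. In wild-type ES cell libraries 1, 2 and 3 Ezh2 was 47.6, 62.5 and 37.2 RPKM, against 23.6, 20.7 and 24.4 RPKM in the mutant (log2 fold change -1.04, SE 0.17, adjusted p = 0.0372). At day 4 Ezh2 was 40.98, 41.6 and 48.3 RPKM in wild-type and 25.2, 22.04 and 26.5 RPKM in mutant libraries, a difference that did not pass (-0.80, SE 0.17, adjusted p = 0.168). At day 8 it was 42.8, 41.4 and 45.8 RPKM in wild type and 18.3, 22.2 and 25.96 RPKM in the mutant (-0.95, SE 0.17, adjusted p = 0.0185). Each mutant library thus lay below each wild-type library of its stage, with reads from the gene still present. RNA values do not show which part of Ezh2 was altered, and the labels give no allele. The ES cell call of Ezh2 was lost without mutant library 1, 2 or 3 or wild-type library 1 or 2. Its day 8 call was lost without mutant library 2 or wild-type library 1 or 2. Transcripts of the core subunits Eed and Suz12 and the paralog Ezh1 did not pass at any stage between mutant and wild type.

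What did the mutation change in undifferentiated ES cells and at day 4? In ES cells 9 genes were higher and 4 lower in the mutant (n = 3 per group). The calcium pump gene Atp2a3 rose from 2.37 ± 1.06 to 10.7 ± 2.67 RPKM (1.82, SE 0.32, adjusted p = 0.0433) and the riboflavin transporter gene Slc52a3 from 1.23 ± 0.541 to 4.45 ± 1.43 RPKM (1.29, SE 0.21, adjusted p = 0.0272). Tmem40 (1.41, SE 0.23, adjusted p = 0.0304), Mllt10 (1.01, SE 0.17, adjusted p = 0.0410) and the adhesion gene Ceacam20 (0.996, SE 0.13, adjusted p = 0.00524) also rose. The largest falls were of the Y-linked genes Eif2s3y, from 46.9 ± 12.9 to 1.42 ± 0.814 RPKM (-4.33, SE 0.33, adjusted p = 1.19e-05), Ddx3y (-3.16, SE 0.42, adjusted p = 0.00498) and Uty (-3.07, SE 0.30, adjusted p = 0.000152). At day 4 the calls were 4 genes up and 3 down, or 16 and 10 with the block. Cdkn2a, a cell-cycle inhibitor locus, rose from 1.37 ± 0.153 to 12.3 ± 4.44 RPKM (2.44, SE 0.38, adjusted p = 0.0215). The homeobox genes En2 (1.37, SE 0.22, adjusted p = 0.0297) and Barx1 (0.998, SE 0.15, adjusted p = 0.0128) rose with it. Eif2s3y (-5.40, SE 0.33, adjusted p = 4.93e-07), Ddx3y and Uty fell again. Pou5f1, the core pluripotency factor, was 408 ± 28.9 RPKM in wild-type and 394 ± 51.4 RPKM in mutant day 4 embryoid bodies and did not pass.

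Those counts rested on few libraries. They were 6 in ES cells and 3 at day 4 by voom, 0 and 1 with only the groups of the contrast, and 0 and 1 without second libraries. In ES cells 5 genes were called without mutant library 2, 4 without mutant library 3 and 5 without wild-type library 2. There Eif2s3y, Ddx3y and Uty held their calls in each fit and Ceacam20 lost its call only without mutant library 3. Atp2a3, Slc52a3, Tmem40 and Mllt10 lost theirs in 3 or more of 6 fits. At day 4 the number was 12 without mutant library 1, 4 without mutant library 2, 4 without wild-type library 2 and 97 without wild-type library 3. The call of Cdkn2a at day 4 was lost without mutant library 1 or 2 or wild-type library 1 or 2, while its log2 fold change lay between 2.20 and 2.49 in those fits. En2 and Barx1 lost their calls without mutant library 2 or 3 or wild-type library 2, and En2 also without wild-type library 1. The imprinted genes had the lowest list median in mutant ES cells (median -0.45, 0 up and 0 down of 37, 0 and 0 adjusted over the list alone, camera adjusted p = 1.07e-05 and 0.818 with an estimated correlation). Trophoblast genes were at a median of -0.40 (camera adjusted p = 0.0297, 0.818 with an estimated correlation). They did not pass at the preset correlation without mutant library 2 (0.0648) or 3 (0.226) or wild-type library 1 (0.157) or 2 (0.147). At day 4 the naive pluripotency genes had a median of 1.12 with 0 up and 0 down of 26 (2 and 0 adjusted over the list alone, camera adjusted p = 1.43e-11, 0.469 with an estimated correlation). Their mean was 5.04 in wild-type library 3 against 3.31 and 3.18 in wild-type libraries 1 and 2 and 4.41, 5.15 and 5.18 in the mutant libraries, on the log2 scale. The primitive streak list was at a median of 0.78 (camera adjusted p = 6.12e-07, 0.479 with an estimated correlation) and was -0.10 without mutant day 4 library 1. The Polycomb-repressed regulators, 2 up and 0 down of 29 (3 and 0 adjusted over the list alone) with Cdkn2a and Barx1 the members called, had a median of 0.26 (camera adjusted p = 4.74e-07, 0.485 with an estimated correlation).

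At day 8, 184 genes were higher and 30 lower in mutant embryoid bodies (n = 3 per group), or 439 and 177 with the block. The count was 39 by voom, 3 with only the groups of the contrast and 6 without second libraries, where 14, 19 and 19 of the 22 named calls were lost. Dnmt3l, a cofactor of de novo DNA methylation, rose from 1.91 ± 2.64 to 30.7 ± 8.81 RPKM (3.79, SE 0.68, adjusted p = 0.0160). The growth factor gene Fgf4 rose from 6.48 ± 9.98 to 52.5 ± 18.5 RPKM (3.74, SE 0.76, adjusted p = 0.0275). Dppa5a (4.20, SE 1.002, adjusted p = 0.0497), Khdc3 (3.59, SE 0.70, adjusted p = 0.0235) and Ooep (3.45, SE 0.73, adjusted p = 0.0334) belong to a family of similar genes whose reads the authors' counting could have split, so these values are uncertain. Cdkn2a rose from 1.41 ± 0.326 to 21.96 ± 10.6 RPKM (3.14, SE 0.38, adjusted p = 0.00150). Its neighbour Cdkn2b also rose (1.88, SE 0.39, adjusted p = 0.0311). Besides the Y-linked Eif2s3y (-5.59, SE 0.33, adjusted p = 2.95e-07), Ddx3y and Uty, falls included the retinoic acid binding gene Crabp2, from 24.97 ± 1.61 to 4.45 ± 3.64 RPKM (-2.44, SE 0.36, adjusted p = 0.00582), and the receptor gene Ror1 (-1.57, SE 0.33, adjusted p = 0.0361). The calls of Cdkn2a, Crabp2, Eif2s3y, Ddx3y and Uty held in each leave-one-out fit. Those of Dnmt3l, Fgf4, Dppa5a, Khdc3, Ooep, Ror1 and Cdkn2b were each lost without mutant library 2 or 3 or wild-type library 1 or 2.

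Wild-type day 8 library 3 differed from the other 2 of its group. Pou5f1 was 27.8, 28.7 and 222 RPKM in wild-type libraries 1, 2 and 3 and 112, 376 and 236 RPKM in the mutant. Its difference did not pass (1.91, SE 0.58, adjusted p = 0.117). Nor did those of Nanog (2.15, SE 0.70, adjusted p = 0.148) and Sox2 (1.73, SE 0.65, adjusted p = 0.208), the other core pluripotency factors. Ezh2 in wild-type library 3 was at the wild-type level, as given above, and its Eif2s3y was 78.8 RPKM, far above the mutant. Across genes, wild-type day 8 library 3 correlated at 0.969 with mutant day 8 library 3 and at 0.904 or less with its own group. Other libraries also correlated more closely with the other genotype than with their own group. Mutant day 8 library 1 did so with wild-type library 2 (0.966, at most 0.934 in its group), wild-type day 4 library 3 with mutant library 3 (0.990 and 0.954) and wild-type ES cell library 3 with mutant library 3 (0.967 and 0.933). By smaller margins the same held for mutant day 8 library 3, mutant day 4 libraries 1 and 3, and library 1 of both wild-type and mutant ES cells. The day 8 count was 1308 without wild-type library 3, 531 without mutant library 1, 52 without mutant library 2, 42 without mutant library 3, 16 without wild-type library 1 and 21 without wild-type library 2.

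Among the lists at day 8, naive pluripotency genes had the highest median between mutant and wild type (median 2.06, 2 up and 0 down of 26, 21 and 0 adjusted over the list alone, camera adjusted p = 1.97e-16 and 0.294 with an estimated correlation). The endoderm list came after the germline list (median 0.80, 8 up and 0 down of 32, 14 and 0 adjusted over the list alone, camera adjusted p = 3.09e-12 and 0.294 with an estimated correlation). The apolipoprotein genes Apoa2 (2.28, adjusted p = 0.00304) and Apob (2.77, adjusted p = 0.0343) and the visceral endoderm gene Amn (2.40, adjusted p = 0.0112) were among the members that rose. Apoa2 kept its call in each leave-one-out fit, whereas Amn lost it without wild-type library 1 or 2 and Apob without mutant library 1 or 3 or wild-type library 1 or 2. Germline genes had a median of 0.97 with 1 up and 1 down of 24 (14 and 1 adjusted over the list alone, camera adjusted p = 4.95e-08, 0.651 with an estimated correlation). The meiotic gene Stra8 rose (1.61, adjusted p = 0.0497) but not without mutant library 2 or 3 or wild-type library 1 or 2. The cardiac list had a median of -0.78 with 0 up and 0 down of 24 (0 and 0 adjusted over the list alone, camera adjusted p = 0.00793, 0.695 with an estimated correlation). The feeder and mesenchyme list had one of -0.65 with 0 up and 0 down of 24 (0 and 0 adjusted over the list alone, camera adjusted p = 0.00748, 0.695 with an estimated correlation). Neither list passed at the preset correlation without mutant library 2 or 3 or wild-type library 1 or 2, at 0.137, 0.222, 0.272 and 0.199 for cardiac muscle and 0.0984, 0.0978, 0.0919 and 0.0767 for feeder fibroblast and mesenchyme. The Polycomb-repressed regulators had a median of -0.28 and a mean of -0.08, while the test pointed up and did not pass (camera adjusted p = 0.731). The change from day 4 to day 8 was tested as a difference between genotypes. For it limma called 0 genes, with 370 at an unadjusted p under 0.05, 0 by voom and 29 without wild-type day 8 library 3. From ES cells to day 4 it called 0, with 276 at an unadjusted p under 0.05 and 0 by voom. In that comparison 1 gene was called without mutant day 4 library 1, wild-type day 4 library 3 or wild-type ES cell library 2. For the later step it was 1 gene without any 1 mutant day 8 library.

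**Figure D1:**
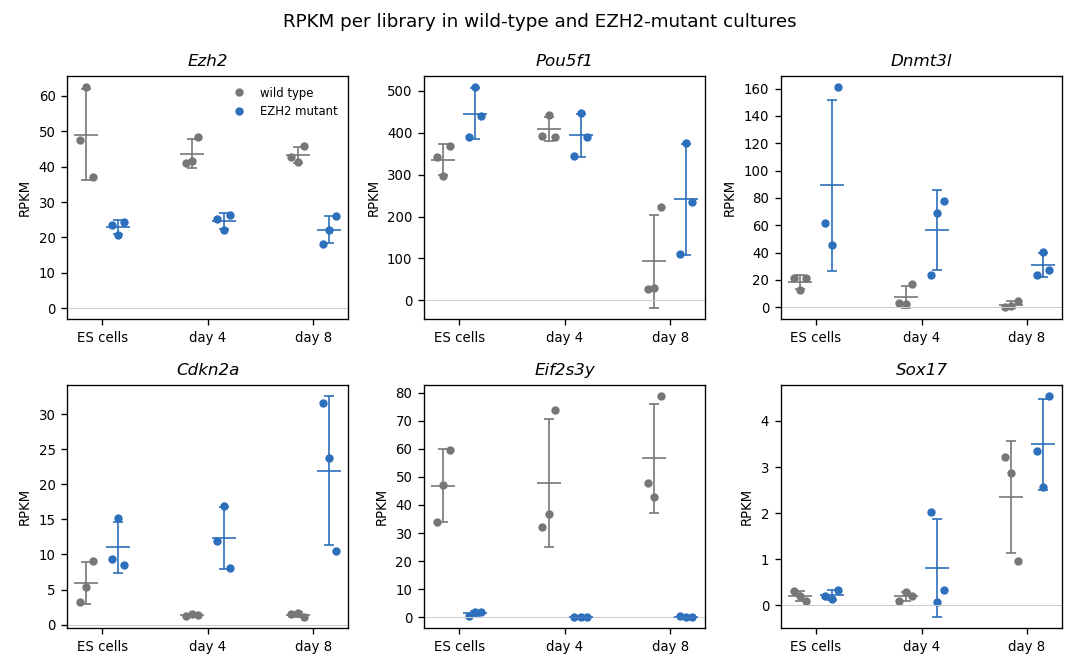
RPKM (vertical axis) of 6 genes in wild-type (grey) and EZH2-mutant (blue) ES cells and embryoid bodies at day 4 and day 8, with points for the 3 libraries of each group and bars for the mean ± SD. Ezh2 and Eif2s3y lie lower in each mutant library, Cdkn2a lies higher in the mutant at day 4 and day 8, and 1 wild-type day 8 library holds Pou5f1 at 222 RPKM.

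Did inhibition of EZH2 give the same changes? With 2 libraries per group, GSK343 changed 0 genes in ES cells (limma, smallest adjusted p = 0.0919), with 669 genes at an unadjusted p under 0.05 and 0 by voom. In leave-one-out fits 16 were called without GSK343 ES cell library 2, the shallowest, and 2 without DMSO ES cell library 2. Ezh2 itself was 47.5 ± 14.7 RPKM in DMSO and 54.5 ± 5.28 RPKM in GSK343 ES cells and did not pass at any stage. The feeder and mesenchyme list had the highest median there (median 0.66, 0 up and 0 down of 24, 7 and 0 adjusted over the list alone, camera adjusted p = 9.06e-11 and 0.514 with an estimated correlation). Its member Lox was at 10.8 ± 0.725 RPKM in DMSO and 23.8 ± 9.70 RPKM in GSK343 (1.02, adjusted p = 0.418), and ES cells were grown on feeder cells. At day 4, 70 genes rose and 18 fell. Dnmt3l rose from 11.97 ± 2.08 to 70.4 ± 2.32 RPKM (2.47, SE 0.17, adjusted p = 0.000498) and held its call in each fit that left out 1 library. The naive pluripotency gene Esrrb rose from 5.17 ± 1.83 to 25.5 ± 2.87 RPKM (2.13, SE 0.27, adjusted p = 0.00949). The muscle genes Mymx (2.82, SE 0.51, adjusted p = 0.0427) and Mylpf (2.21, SE 0.38, adjusted p = 0.0354) and the uridine phosphorylase gene Upp1 (2.12, SE 0.24, adjusted p = 0.00723) rose as well. Prickle1, of the planar polarity pathway, fell from 13.8 ± 2.26 to 3.74 ± 0.371 RPKM (-1.64, SE 0.22, adjusted p = 0.0124), as did the zinc transporter gene Slc39a8, Mir18b, Mcoln3 and Chst1. Cdkn2a rose from 3.25 ± 1.25 to 12.2 ± 1.93 RPKM (1.65, SE 0.26, adjusted p = 0.0267), whereas Pou5f1 was 585 ± 86.6 and 596 ± 86.6 RPKM.

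By voom the day 4 count was 57, and with only the groups of the contrast 145. With 2 libraries per group it fell to 3 without GSK343 library 1, 10 without GSK343 library 2, 21 without DMSO library 1 and 1 without DMSO library 2. The lone library is taken to vary like the other groups in such fits. Esrrb and Upp1 lost their calls without either GSK343 library or DMSO library 2. Mymx, Mylpf, Prickle1, Slc39a8, Mir18b, Mcoln3, Chst1 and Cdkn2a lost theirs without any 1 of the 4 libraries. Naive pluripotency genes had the highest list median at day 4 (median 1.07, 10 up and 0 down of 26, 18 and 0 adjusted over the list alone, camera adjusted p = 7.21e-23 and 0.188 with an estimated correlation). Nr5a2 (1.97, adjusted p = 0.00922), Klf2 (1.78, adjusted p = 0.0177) and Zfp42 (1.88, adjusted p = 0.0177) were among those that rose, but Nr5a2 and Klf2 lost their calls without either GSK343 library or DMSO library 2 and Zfp42 without any 1 of the 4. Germline genes were at a median of 0.31 (camera adjusted p = 6.59e-05, 0.613 with an estimated correlation) and p53 targets at 0.21 (camera adjusted p = 0.00103, 0.613 with an estimated correlation). Without GSK343 library 1 the median of the p53 targets was -0.00850 and the list did not pass (0.629).

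At day 8 GSK343 raised 2193 genes and lowered 2241. The count of changed genes was 4553 by voom and 2704 with only the groups of the contrast. Pou5f1 was 443 ± 31.1 RPKM under GSK343 against 57.7 ± 4.49 RPKM in DMSO (2.92, SE 0.17, adjusted p = 1.37e-06). Sox2 was 170.4 ± 33.9 against 18.04 ± 1.83 RPKM (3.16, SE 0.17, adjusted p = 1.08e-06). Nanog rose as well (2.54, SE 0.25, adjusted p = 5.46e-05). The largest rises were of Dnmt3l, from 1.32 ± 0.233 to 70.8 ± 13.3 RPKM (4.94, SE 0.17, adjusted p = 5.68e-08), and of the Nodal antagonist gene Lefty2 (4.44, SE 0.26, adjusted p = 1.42e-06). They also took in Zfp42, a marker of naive ES cells (4.36, SE 0.27, adjusted p = 2.42e-06), and the noncoding Platr10 (4.31, SE 0.17, adjusted p = 1.45e-07). Rpl39l rose too (4.37, SE 0.45, adjusted p = 7.13e-05) but could share reads with a near-identical gene. The embryonic globin genes Hbb-bh1, from 340.5 ± 261 to 0.126 ± 0.0722 RPKM (-7.997, SE 0.48, adjusted p = 1.90e-06), and Hba-x (-5.04, SE 0.43, adjusted p = 2.13e-05) fell as well, and they too have close copies. Hand2, a transcription factor of the early heart, fell from 46.3 ± 5.70 to 0.156 ± 0.153 RPKM (-5.35, SE 0.14, adjusted p = 1.49e-08). The receptor gene Nrp1 fell from 119 ± 25.01 to 0.996 ± 0.958 RPKM (-5.98, SE 0.33, adjusted p = 1.08e-06) and the troponin gene Tnni1 from 61.6 ± 28.1 to 0.757 ± 0.435 RPKM (-5.10, SE 0.27, adjusted p = 9.29e-07). Cdkn2a was 14.9 ± 0.662 against 3.22 ± 0.442 RPKM (1.92, SE 0.26, adjusted p = 0.000405). Among germ layer regulators Gata4 fell (-2.22, SE 0.52, adjusted p = 0.00905), Sox17 fell (-1.76, SE 0.52, adjusted p = 0.0259) and Pax6 rose (0.51, SE 0.14, adjusted p = 0.0170), while T did not pass. The call of Gata4 was lost without DMSO library 1, that of Sox17 without GSK343 library 2 or either DMSO library, and that of Pax6 without GSK343 library 1 or DMSO library 2. The count was 2732 without DMSO day 8 library 2.

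**Figure D2:**
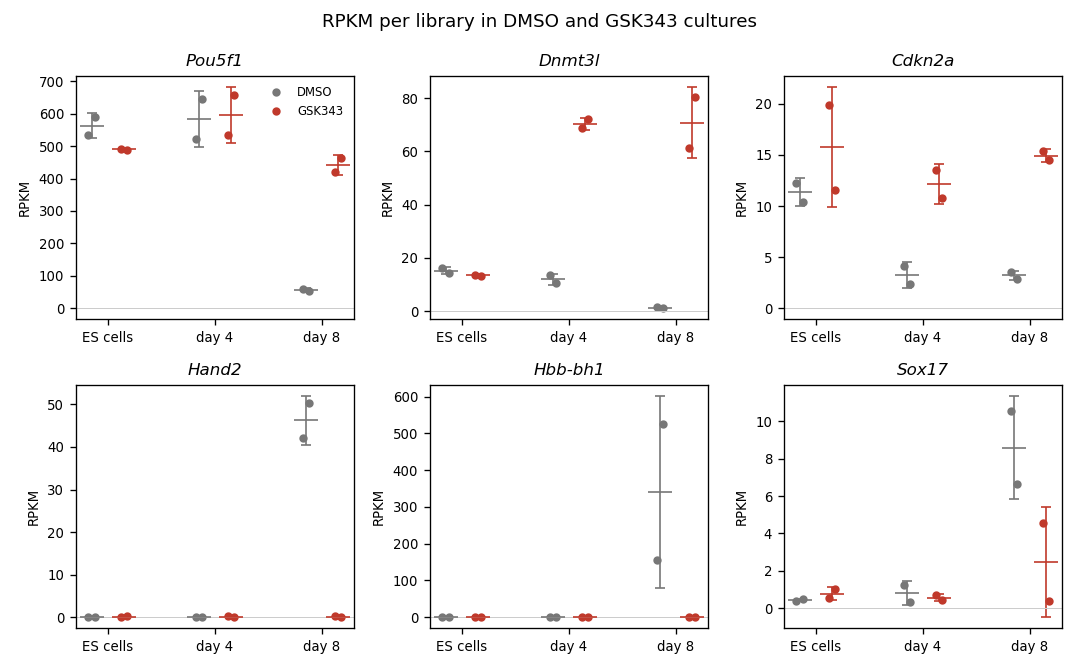
RPKM (vertical axis) of 6 genes in DMSO (grey) and GSK343 (red) ES cells and embryoid bodies at day 4 and day 8, with points for the 2 libraries of each group and bars for the mean ± SD. Pou5f1 and Dnmt3l stay high under GSK343 at day 8, while Hand2 and Hbb-bh1 are near 0 there.

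The lists moved apart at day 8. Naive pluripotency genes had a median of 3.04 with 22 up and 0 down of 26 (22 and 1 adjusted over the list alone, camera adjusted p = 2.14e-15, 0.1002 with an estimated correlation). Among them Utf1 rose from 6.46 ± 0.527 to 126 ± 8.87 RPKM. Formative genes had a median of 1.46 with 8 up and 1 down of 13 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00673, 0.443 with an estimated correlation). Foxd3 (3.57, adjusted p = 5.82e-05) and Otx2 (2.75, adjusted p = 0.000103) rose. Germline genes had a median of 1.55 with 18 up and 1 down of 23 (19 and 1 adjusted over the list alone, camera adjusted p = 1.85e-08, 0.107 with an estimated correlation). The meiotic recombinase gene Dmc1 (2.19, adjusted p = 3.29e-05), Mael (2.83, adjusted p = 0.000209) and Piwil2 (2.05, adjusted p = 1.49e-05) rose. Cardiac genes had a median of -1.87 with 1 up and 16 down of 21 (2 and 17 adjusted over the list alone, camera adjusted p = 5.60e-09, 0.0697 with an estimated correlation). Its member Hand1 fell by 4.98. Blood and endothelial genes had a median of -1.75 with 1 up and 20 down of 22 (2 and 20 adjusted over the list alone, camera adjusted p = 1.99e-10, 0.108 with an estimated correlation). The endothelial receptor gene Kdr fell by 4.29. Hox genes had a median of -1.37 with 0 up and 11 down of 15 (0 and 11 adjusted over the list alone, camera adjusted p = 9.94e-09, 0.0697 with an estimated correlation). Hoxb2 (-3.26, adjusted p = 9.32e-07) and Hoxb3 (-2.47, adjusted p = 3.52e-07) fell. The Polycomb-repressed regulators had a median of -0.85 with 4 up and 22 down of 31 (5 and 22 adjusted over the list alone, camera adjusted p = 6.31e-08, 0.1002 with an estimated correlation). There Msx2 (-4.35, adjusted p = 2.71e-07), Tbx2 (-3.98, adjusted p = 2.38e-07) and Foxf1 (-3.51, adjusted p = 3.25e-08) fell.

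Endoderm genes had a median of -1.45 with 1 up and 18 down of 30 (1 and 22 adjusted over the list alone, camera adjusted p = 1.19e-08, 0.248 with an estimated correlation). Ttr (-4.74, adjusted p = 1.47e-05), Afp (-3.29, adjusted p = 1.49e-06) and Rbp4 (-3.39, adjusted p = 2.42e-06) fell. Imprinted genes were at -0.80 with 4 up and 17 down of 37 (4 and 18 adjusted over the list alone, camera adjusted p = 1.24e-05, 0.160 with an estimated correlation). Dlk1 fell (-3.46, adjusted p = 2.76e-07), and Airn, antisense to another imprinted gene, cannot be separated from its partner because the use of strand is not stated. Feeder and mesenchyme genes were at -1.41 with 0 up and 14 down of 24 (0 and 16 adjusted over the list alone, camera adjusted p = 4.41e-06, 0.301 with an estimated correlation). Trophoblast genes were at -0.67 with 0 up and 7 down of 14 (1 and 8 adjusted over the list alone, camera adjusted p = 0.00934, 0.1002 with an estimated correlation). Primitive streak genes were at -0.54 with 1 up and 5 down of 19 (1 and 7 adjusted over the list alone, camera adjusted p = 0.0398, 0.609 with an estimated correlation). Of these Nodal rose (2.73, adjusted p = 3.09e-06) and Mesp1 fell (-4.34, adjusted p = 0.000181). Neural genes were at 0.51 with 7 up and 3 down of 15 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0357, 0.443 with an estimated correlation), with Tubb3 up (2.78, adjusted p = 2.21e-06) and Irx3 down (-2.86, adjusted p = 3.28e-06). Hypoxia and glycolysis genes were at -0.48 with 1 up and 8 down of 24 (1 and 11 adjusted over the list alone, camera adjusted p = 0.00673, 0.412 with an estimated correlation). PRC2 subunit genes were at 0.38 with 4 up and 2 down of 12 (4 and 2 adjusted over the list alone, camera adjusted p = 0.196). PRC1 subunit genes were at -0.09 with 5 up and 7 down of 22 (5 and 7 adjusted over the list alone, camera adjusted p = 0.753) and cell division genes at 0.16 with 1 up and 0 down of 28 (0 and 0 adjusted over the list alone, camera adjusted p = 0.114). The p53 targets had a median of -0.13, a mean of 0.10 and a test pointing up, with 3 up and 1 down of 20 (3 and 1 adjusted over the list alone, camera adjusted p = 0.753). Ribosomal protein genes were at a median of -0.05 and a mean of -0.01 with the test pointing up, 0 up and 0 down of 32 (0 and 0 adjusted over the list alone, camera adjusted p = 0.984). With an estimated correlation none of these GSK343 day 8 lists passed. At the preset correlation the formative (0.0893), trophoblast (0.0743) and hypoxia (0.141) lists did not pass without GSK343 library 1, nor the primitive streak list without GSK343 library 2 (0.754) or DMSO library 1 (0.422), nor the neural list without GSK343 library 1 (0.243) or DMSO library 2 (0.0778). The 2-cell-like and mitochondrially encoded lists had no member tested.

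How far did the mutant and the inhibitor change the same genes? At day 8, 123 genes were up in both among 13792 tested in both tables, where the 177 mutant and 2165 GSK343 calls would share 27.8 if independent (one-sided Fisher's exact p = 1.31e-58 over genes, which are not independent). Down in both were 14 genes, against 4.77. At day 4 the pair of genes up in both were Cdkn2a and 1700030C10Rik, against 0.0203. In ES cells there were 0 because GSK343 had no calls. Fold changes of the 4421 genes called at day 8 in either comparison correlated at a Pearson's r of 0.780 and a Spearman's rho of 0.814 across genes, with 8 genes called in opposite directions. Over all 13792 genes r was 0.699 at day 8, 0.713 at day 4 and 0.157 in ES cells. The endoderm list's day 8 median was positive in the mutant but negative under GSK343. The comparisons share no control libraries. Mutant day 8 calls were 214, but 39 by voom and 3 with only the groups of the contrast, and the overlap was not recounted there. A split of these libraries not by genotype gave 2916 calls. The overlap and correlation were not tested apart from such structure.

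The inhibitor's effect at day 8 can be set against the course of differentiation. In DMSO, 2395 genes rose and 2203 fell from ES cells to day 4, and 3262 rose and 2536 fell from day 4 to day 8, or 2386 and 3720 with each library centred on its median. The naive gene Klf4 fell from 53.2 ± 2.78 to 1.34 ± 0.343 RPKM by day 4 (-4.54, SE 0.23, adjusted p = 9.97e-06). The formative gene Fgf5 rose from 0.0872 ± 0.0683 to 25.9 ± 1.46 RPKM (4.63, SE 0.41, adjusted p = 6.73e-05). By day 8 Pou5f1 had fallen from 585 ± 86.6 to 57.7 ± 4.49 RPKM (-3.31, SE 0.17, adjusted p = 5.36e-07) and Hand2 had risen from 0.0207 ± 0.0293 to 46.3 ± 5.70 RPKM (5.53, SE 0.14, adjusted p = 1.03e-08). Under GSK343, 1367 genes rose and 1722 fell from ES cells to day 4 (1774 and 1392 with centring), with Klf4 down (-3.37, SE 0.23, adjusted p = 3.13e-05) and Zic2 up (4.41, SE 0.30, adjusted p = 2.78e-05). GSK343 embryoid bodies had 91 rises and 8 falls from day 4 to day 8, or 31 and 10 with centring. The count was 63 by voom and 0 with only the groups of the contrast. There were 2627 genes at an unadjusted p under 0.05, against 6974 in DMSO. Pou5f1 was 596 ± 86.6 RPKM at day 4 and 443 ± 31.1 RPKM at day 8 (-0.42, SE 0.17, adjusted p = 0.218). Hand2 was 0.138 ± 0.0602 and 0.156 ± 0.153 RPKM. Among the genes that did change, the hypoxia genes Egln3 (2.54, SE 0.17, adjusted p = 0.000386) and Ndrg1 (2.53, SE 0.21, adjusted p = 0.00193) and the imprinted H19 (3.29, SE 0.38, adjusted p = 0.00859) rose. Egln3 held its call in each fit that left out 1 library, Ndrg1 lost it without day 4 library 2 and H19 without day 4 library 1 or 2, and none of the 3 passed with only the groups of the contrast. The hypoxia list had a median of 1.07 with 9 up and 0 down of 24 (20 and 0 adjusted over the list alone, camera adjusted p = 6.34e-18, 0.0754 with an estimated correlation). In DMSO it was 1.88 with 21 up and 0 down of 24 (21 and 0 adjusted over the list alone, camera adjusted p = 7.60e-10, 0.0995 with an estimated correlation).

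In the same step of DMSO cultures the cardiac list had a median of 2.56 with 19 up and 1 down of 21 (19 and 1 adjusted over the list alone, camera adjusted p = 7.60e-10, 0.0474 with an estimated correlation). The Hox list had 1.46 with 11 up and 0 down of 15 (11 and 0 adjusted over the list alone, camera adjusted p = 4.87e-07, 0.0474 with an estimated correlation) and the trophoblast list 1.41 with 10 up and 0 down of 14 (12 and 0 adjusted over the list alone, camera adjusted p = 6.81e-05, 0.0474 with an estimated correlation). Under GSK343 the medians were 0.35 for cardiac genes (camera adjusted p = 0.00708, 0.429 with an estimated correlation), -0.02 for Hox genes (camera adjusted p = 0.543, 0.980 with an estimated correlation) and 0.67 for trophoblast genes (camera adjusted p = 0.00114, 0.0754 with an estimated correlation). The difference between these steps was tested itself. From day 4 to day 8, 796 genes changed more upward and 913 more downward under GSK343 than in DMSO. The cardiac (median -1.93, 0 up and 12 down of 21, 1 and 16 adjusted over the list alone, camera adjusted p = 4.07e-12 and 0.0328 with an estimated correlation), Hox (median -1.45, 0 up and 11 down of 15, 0 and 11 adjusted over the list alone, camera adjusted p = 4.33e-12 and 0.0320 with an estimated correlation) and Polycomb-repressed lists (median -1.03, 0 up and 20 down of 31, 1 and 21 adjusted over the list alone, camera adjusted p = 1.29e-13 and 0.0431 with an estimated correlation) passed with either correlation. From ES cells to day 4 the difference held for 3 genes, Dnmt3l, Ltb and Nphs1.

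The counts of these steps moved when 1 library was left out. For DMSO from ES cells to day 4 they were 2306 without day 4 library 1, 2133 without day 4 library 2 and 2275 without ES cell library 2, and from day 4 to day 8 3639 without day 4 library 2. For GSK343 from ES cells to day 4 they were 1527 without day 4 library 1, 1822 without day 4 library 2 and 1238 without ES cell library 2. For GSK343 from day 4 to day 8 they were 1610 without day 8 library 1, 39 without day 8 library 2, 6 without day 4 library 1 and 1 without day 4 library 2. The GSK343 day 8 libraries differed from each other, with Dnmt3b at 349 and 88.7 RPKM in libraries 1 and 2. Library 1 correlated more closely with GSK343 day 4 library 1 (0.988) than with library 2 (0.971). The day 4 to day 8 difference between treatments was called for 996 genes without GSK343 day 4 library 1, 1076 without DMSO day 8 library 2, 896 without DMSO day 4 library 1 and 847 without DMSO day 4 library 2. The ES cell to day 4 difference was called for 0 genes without GSK343 day 4 library 1 or 2, GSK343 ES cell library 1 or 2, DMSO day 4 library 2 or DMSO ES cell library 1, and for 1 gene without DMSO day 4 library 1.

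Wild-type and mutant cells went through the same stages with 3 libraries each. From ES cells to day 4, 608 genes rose and 622 fell in wild type and 440 rose and 463 fell in the mutant. With the block the counts were 1238 and 1038 in wild type and 978 and 830 in the mutant. Klf4 fell in both (-3.83, SE 0.44, adjusted p = 0.000189 and -3.30, SE 0.44, adjusted p = 0.000756), and Sall2, a formative gene, rose in both (3.88, SE 0.37, adjusted p = 6.00e-05 and 3.002, SE 0.37, adjusted p = 0.000435). The formative list had a median of 2.16 in wild type with 10 up and 0 down of 13 (11 and 0 adjusted over the list alone, camera adjusted p = 3.42e-10, 0.0759 with an estimated correlation). In the mutant it was 2.08 with 8 up and 0 down of 13 (10 and 0 adjusted over the list alone, camera adjusted p = 1.23e-10, 0.0657 with an estimated correlation). From day 4 to day 8, 1501 genes rose and 1441 fell in wild type (1240 and 1798 with centring), and 849 rose and 617 fell in the mutant (721 and 776 with centring). With the block these were 2333 and 2569 in wild type and 1465 and 1762 in the mutant. The hypoxia gene Adm rose in both (3.64, SE 0.18, adjusted p = 3.18e-08 and 3.98, SE 0.18, adjusted p = 8.34e-09). Endoderm genes had a median of 1.41 in wild type with 19 up and 0 down of 32 (20 and 0 adjusted over the list alone, camera adjusted p = 1.72e-08, 0.390 with an estimated correlation) and 2.33 in the mutant with 23 up and 0 down of 32 (25 and 0 adjusted over the list alone, camera adjusted p = 5.18e-21, 0.0685 with an estimated correlation). Spink1 rose in both (4.02, SE 0.65, adjusted p = 0.00169 and 6.16, SE 0.65, adjusted p = 7.97e-05). The cardiac list was at 2.14 in wild type with 15 up and 0 down of 24 (18 and 1 adjusted over the list alone, camera adjusted p = 6.31e-08, 0.440 with an estimated correlation). In the mutant it was at 1.03 with 4 up and 0 down of 24 (5 and 0 adjusted over the list alone, camera adjusted p = 0.000171, 0.680 with an estimated correlation). As given above, limma called no gene for the difference between genotypes in either step.

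In wild type the counts from ES cells to day 4 were 774 by voom, 217 with only the groups of the contrast and 1 without second libraries, and on to day 8 they were 2160, 975 and 21. In the mutant they were 934, 1053 and 6, then 1256, 680 and 87. Without second libraries 37 of 37 and 34 of 34 named calls from ES cells to day 4 were lost in wild type and mutant, Klf4 and Sall2 among them, and 62 of 65 and 29 of 40 from day 4 to day 8, with Spink1 among those of wild type. With only the groups of the contrast 26 of 37 and 7 of 34 were lost in the first step and 38 of 65 and 12 of 40 in the second, but none of Klf4, Sall2, Adm and Spink1 in these steps. The counts also moved with single libraries. In wild type from ES cells to day 4 they were 357 and 362 without day 4 library 1 or 2 and 669 and 587 without ES cell library 1 or 2. From day 4 to day 8 they were 828 and 996 without day 8 library 1 or 2 and 1544 and 1520 without day 4 library 1 or 2. In the mutant from ES cells to day 4 they were 323 and 505 without day 4 library 1 or 2 and 600, 406 and 419 without ES cell library 1, 2 or 3. From day 4 to day 8 in the mutant they were 609 and 870 without day 8 library 1 or 3 and 929, 510 and 873 without day 4 library 1, 2 or 3.

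Replating asked whether differentiated cells keep their identity in ES cell medium. The comparisons gave 0 genes past the threshold with limma and 0 with voom. Against DMSO then DMSO there were 3385 genes at an unadjusted p under 0.05 for GSK343 then DMSO (smallest adjusted p = 0.169), 328 for DMSO then GSK343 (0.885) and 2184 for GSK343 then GSK343 (0.319). GSK343 then GSK343 against GSK343 then DMSO had 196 and the interaction of the treatments 187. Values are therefore given without a call. The fold changes given here are not corrected for the median of all genes. Those medians were -0.23 for DMSO then GSK343 and -0.17 for GSK343 then GSK343 against DMSO then DMSO, -0.11 for GSK343 then GSK343 against GSK343 then DMSO and 0.13 for the interaction. Pou5f1 was 104, 0.997 and 4.67 RPKM in DMSO then DMSO, 1.80, 1.10 and 1.81 RPKM in DMSO then GSK343, 188, 224 and 176 RPKM in GSK343 then DMSO and 74.7 and 220.04 RPKM in GSK343 then GSK343. Dppa5a, which has near-identical copies, was 1.40 ± 1.26 RPKM in DMSO then GSK343 and 247 ± 22.99 RPKM in GSK343 then GSK343. Cdkn2a was 97.4 ± 38.4 RPKM in DMSO then DMSO and 62.4 ± 41.9 RPKM in GSK343 then DMSO, and Ezh2 was 9.68 ± 9.89 and 25.2 ± 14.9 RPKM there. Hoxa9 was 1.01 ± 0.505 RPKM in DMSO then DMSO and 0.622 ± 0.419 RPKM in GSK343 then DMSO.

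DMSO then DMSO library 1 stood apart from libraries 2 and 3 in Pou5f1 and correlated best, at 0.951, with GSK343 then GSK343 library 1. Without it GSK343 then DMSO had 595 calls, 567 up and 28 down, and GSK343 then GSK343 had 236. Without GSK343 then GSK343 library 1 the group had 1410 calls against DMSO then DMSO and 2124 against DMSO then GSK343. The latter comparison was added because the authors' deposited table holds it, and it gave 0 calls with all libraries. There 2633 genes had an unadjusted p under 0.05 (smallest adjusted p = 0.115, 0 by voom). In the fit of DMSO then DMSO and GSK343 then DMSO alone, 376 genes were up and 620 down.

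Lists were tested in the same way in replated cells. Against DMSO then DMSO, GSK343 then DMSO had a naive pluripotency median of 2.52 with 0 up and 0 down of 26 (21 and 1 adjusted over the list alone, camera adjusted p = 3.87e-13, 0.373 with an estimated correlation). Its cell division median was 2.02 with 0 up and 0 down of 28 (25 and 0 adjusted over the list alone, camera adjusted p = 1.83e-14, 0.373 with an estimated correlation). Its Hox median was -0.89 (camera adjusted p = 1.24e-05, 0.373 with an estimated correlation) and its feeder and mesenchyme median -1.02 (camera adjusted p = 0.000271, 0.379 with an estimated correlation). GSK343 then GSK343 against DMSO then GSK343 gave 3.74 for naive pluripotency with 0 up and 0 down of 26 (25 and 0 adjusted over the list alone, camera adjusted p = 2.05e-20, 0.388 with an estimated correlation). For cell division it gave 2.73 with 0 up and 0 down of 28 (26 and 0 adjusted over the list alone, camera adjusted p = 1.00e-18, 0.388 with an estimated correlation). In DMSO then GSK343 against DMSO then DMSO, the comparison that adds the inhibitor after differentiation, the naive pluripotency median was -1.50 with 0 up and 0 down of 26 (0 and 0 adjusted over the list alone, camera adjusted p = 8.45e-09, 0.583 with an estimated correlation). There the cell division median was -1.17 (camera adjusted p = 2.03e-10, 0.583 with an estimated correlation), the Hox median 0.13 (camera adjusted p = 0.000267, 0.632 with an estimated correlation) and the Polycomb-repressed median 0.20 (camera adjusted p = 0.000267, 0.583 with an estimated correlation). These calls followed DMSO then DMSO library 1. Without it the medians were -0.35 for naive pluripotency (camera adjusted p = 0.176), -0.38 for cell division (0.0703), -0.0930 for Hox (0.426) and 0.12 for the Polycomb-repressed list (0.0703).

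**Figure D3:**
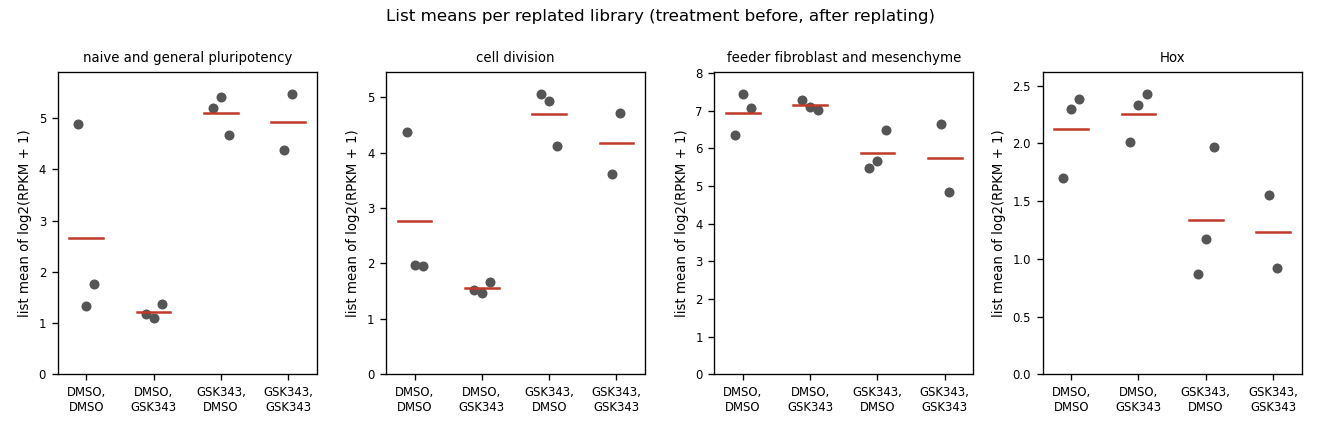
Mean of log2(RPKM + 1) over the members of 4 gene lists (vertical axis) in each replated library, with points for libraries, a red line for the group mean and groups named by the treatment before and after replating. In the naive pluripotency panel each GSK343-started library lies above each DMSO then GSK343 library, while 1 DMSO then DMSO library lies apart from the other 2.

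Genes that the authors' deposited table calls PRC2 targets were compared with the other genes as the test of whether loss of EZH2 activity raised them. Of 4774 such genes with a span, 85.9% lay within 1 kb of a merged wild-type H3K27me3 peak, against 5.21% of 10040 others. At mutant day 8, 78 targets rose and 14 fell of 4090 tested, against 106 and 16 of 10090 other genes. The targets' median log2 fold change was -0.03 against -0.02 in other genes (camera p = 0.954, 0.972 with an estimated correlation). The camera p was 0.183 in mutant ES cells and 0.660 at mutant day 4. Under GSK343 it was 0.140 in ES cells and 0.249 at day 4. There 36 targets rose and 11 fell of 4038, against 34 and 7 of 9978 other genes. At day 8 under GSK343, 665 targets rose and 1018 fell of 4038, against 1528 and 1223 of 9978 other genes. The targets' median was -0.06 against 0.02 (camera p = 0.0339, 0.127 with an estimated correlation). Without GSK343 day 8 library 2 the p was 0.150. In these counts a larger share of targets than of other genes was called in both directions, which camera does not measure and which was not tested. Beside random lists of matched expression, the targets' median was higher than 0% of lists in mutant ES cells, 82.9% at mutant day 4 and 56.5% at mutant day 8, and 0% in GSK343 ES cells, at day 4 and at day 8. Such lists draw genes as if independent and leave out the spread between libraries. A small shift, such as -0.038 against -0.015 at GSK343 day 4, can thus reach 0%. In wild type the targets rose relative to other genes from day 4 to day 8 (camera p = 0.0391, 0.220 with an estimated correlation), and likewise in the mutant (0.0342 and 0.209). In DMSO then GSK343 against DMSO then DMSO the targets had a median of -0.08 against -0.29 (camera p = 1.46e-06, 0.0376 with an estimated correlation). Other single libraries moved the ES cell and day 4 values past 0.05, to 0.0410 without mutant ES cell library 2, 0.0433 without mutant day 4 library 3 and 0.0377 without DMSO ES cell library 1. In replated cells the p of GSK343 then DMSO against DMSO then DMSO was 0.0522, and 0.00341 without GSK343 then DMSO library 3 and 0.0109 without DMSO then DMSO library 1. Cdkn2a, on chromosome 4 at 89274473 to 89294619 of mm10, lay inside an H3K27me3 peak at 89264529 to 89316559.

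CUT&RUN, which maps chromatin proteins by cleavage at antibody-bound sites, was represented by 4 peak sets merged over the wild-type stages and 9 Suz12 peak lists of single libraries. The H3K27me3 set held 11884 peaks covering 94199 kb, the set of Ring1B, a PRC1 subunit, 782, that of Suz12 491 and that of Ezh2 450. Of the Ezh2 peaks 90.9% (95% Wilson interval 87.9 to 93.2) overlapped an H3K27me3 peak, of the Suz12 peaks 92.1% (89.3 to 94.1) and of the Ring1B peaks 69.6% (66.3 to 72.7). Such intervals cover counting error and no other error. Ezh2 peaks overlapped Suz12 peaks in 66.2% (61.7 to 70.4) and Ring1B peaks in 69.8% (65.4 to 73.8) of cases. Of 5651 peaks of mutant ES cell library 1, 3.42% overlapped library 2, at mutant day 4 the share was 2.08% of 5963 and at mutant day 8 5.51% of 3322. Mutant libraries 1 and 2 overlapped the wild-type list of their stage in 2.44% and 5.85% of peaks in ES cells, 0.335% and 0.783% at day 4 and 6.89% and 23.1% at day 8. Overlap with merged H3K27me3 peaks was 3.73% of 8493 peaks in wild-type ES cells, 9.90% of 1000 at day 4 and 40.5% of 6511 at day 8, where each stage had 1 list. In the mutant it was 19.6% and 5.53% in ES cells, 13.1% and 11.3% at day 4 and 13.1% and 31.6% at day 8 in libraries 1 and 2. The shortest peaks were 1001 bp in wild-type lists and 487 to 501 bp in mutant lists, so no difference between genotypes is read from these shares. The overlap of randomly placed peaks was not computed and each wild-type stage had 1 list. No change between stages is therefore read either.

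For the same steps the authors' deposited table has 2317 rises and 2486 falls from DMSO ES cells to day 4, and 3051 and 2579 on to day 8. For GSK343 the authors' deposited table gives 1749 and 1682, then 1026 and 186. For wild type the authors' deposited table has 763 and 1188, then 1660 and 859, and for the mutant 1043 and 804, then 1348 and 356. Of the genes called here, those also called with the same sign in the authors' deposited table were 3639 of 4598 and 4610 of 5798 for DMSO, 2388 of 3089 and 90 of 99 for GSK343, 844 of 1230 and 1492 of 2942 for wild type, and 640 of 903 and 672 of 1466 for the mutant. For replated cells the authors' deposited table has 682 genes higher and 429 lower in GSK343 then DMSO than in DMSO then DMSO, and 1258 higher and 97 lower in GSK343 then GSK343 than in DMSO then GSK343, where limma on these values called 0.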

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

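The tests of a mixture of cells and of a single library behind the pattern were chosen only after the result was seen. A test of the difference itself picked out effects of time that differed between GSK343 and DMSO. From ES cells to day 4 there were 3 such genes, Dnmt3l (2.63, limma adjusted p = 0.00761), Ltb (1.88, 0.0252) and Nphs1 (1.82, 0.0252). From day 4 to day 8 there were 1709. Of the named genes, Platr10 (4.64), Mir18b (3.55), Lefty2 (3.45), Pou5f1 (2.89), Nanog (2.61), Dnmt3l (2.48), Zfp42 (2.47), Sox2 (2.44), Rpl39l (2.44), Chst1 (1.41) and Esrrb (1.37) changed more upward under GSK343, and Tnni1 (-5.23), Hba-x (-5.28), Hand2 (-5.51), Nrp1 (-6.09) and Hbb-bh1 (-8.48) more downward, with limma adjusted p from 4.75e-07 for Hand2 to 0.0413 for Esrrb. The cardiac (median -1.93), Hox (-1.45) and Polycomb-repressed (-1.03) lists passed with the estimated correlation, at adjusted p of 0.0328, 0.0320 and 0.0431.

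The pattern weighed here is that pluripotency genes were higher in GSK343 than in DMSO embryoid bodies at day 8. A mixture of undifferentiated ES cells and normally differentiated day 8 cells is argued against by the formative and primed genes, which would lie between the levels of the ES cells and the DMSO embryoid bodies. They exceeded the higher of these by a median of 1.56 in GSK343 library 1 and 0.827 in library 2 on the log2 scale, with 10 and 7 of 13 genes above. That 1 of the GSK343 day 8 libraries alone carries the difference is argued against by 23 of 26 members with both GSK343 libraries above both DMSO libraries. What stays open is an effect of the inhibitor on differentiation, which was not tested apart from slower progress of the same cultures. With 2 libraries per group no other split of the samples was counted.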

How the results depend on the processing

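The voom fits, the fits without second libraries, camera with an estimated correlation, gene spans near H3K27me3 peaks in place of the authors' call, the comparison of GSK343 then GSK343 with DMSO then GSK343 and the replated fits without DMSO then DMSO library 1 were chosen only after the data were seen. The cause was not tested for the changes listed here. Starts within 5 kb of a peak or inside a peak were not run, since starts could not be read from spans. Where 1 library of a group of 2 was left out, the lone library is assumed to vary like the other groups.

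With only the groups of the contrast in the fit, counts for mutant against wild type were 0 in ES cells, 1 at day 4 and 3 at day 8, for GSK343 against DMSO 145 at day 4 and 2704 at day 8, for wild type 217 from ES cells to day 4 and 975 from day 4 to day 8, for the mutant from day 4 to day 8 680, for GSK343 from day 4 to day 8 0, for the differences of change from ES cells to day 4 2 in the mutant and 11 under GSK343, and for replated cells 996 for GSK343 then DMSO against DMSO then DMSO, 1 for GSK343 then GSK343 against GSK343 then DMSO and 105 against DMSO then GSK343.

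With voom on recovered reads the counts were 6, 3 and 39 for mutant against wild type in ES cells, at day 4 and at day 8, 57 for GSK343 at day 4, 774 for wild type from ES cells to day 4 and 63 for GSK343 from day 4 to day 8. With no second libraries in the wild-type and mutant table they were 0, 1 and 6 for mutant against wild type, 1 and 21 for wild type from ES cells to day 4 and on to day 8, and 6 and 87 for the mutant. List medians that changed sign there included hypoxia in mutant ES cells (0.10), blood at mutant day 8 (0.00977), hypoxia in the mutant difference from ES cells to day 4 (-0.0739) and Hox in that from day 4 to day 8 (0.0417). With a filter at 2 RPKM the counts were 3 in mutant ES cells and 142 at mutant day 8. With a pseudocount of 0.1 there was 1 call each for GSK343 then DMSO and GSK343 then GSK343 against DMSO then DMSO and for GSK343 then GSK343 against DMSO then GSK343. With no filter 1 gene was called for the mutant difference from ES cells to day 4. With libraries centred on their median the counts were 41 for GSK343 from day 4 to day 8 and 1 for the mutant difference from ES cells to day 4. With a minimum log2 fold change of 1, 4 genes were down in both mutant and GSK343 at day 8.

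The camera p of PRC2 targets at GSK343 day 8 was 0.0609 with a pseudocount of 0.1 and 0.127 with the estimated correlation. For GSK343 then DMSO against DMSO then DMSO it was 0.0457 with a pseudocount of 0.1, 0.00836 with a filter at 2 RPKM, 0.0448 with eBayes without the trend and 0.0395 with gene spans near H3K27me3 peaks (0.340 with the estimated correlation). For GSK343 then GSK343 against DMSO then DMSO it was 0.0477 with a pseudocount of 0.1 and 0.0118 with a filter at 2 RPKM, and against DMSO then GSK343 0.0643 with the estimated correlation. Gene spans near H3K27me3 peaks gave 0.0409 in mutant ES cells (0.343 with the estimated correlation) and 0.00401 in GSK343 ES cells (0.0484), both downward.

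With the replicate number as a block the counts were 41, 26 and 616 for mutant against wild type in ES cells, at day 4 and at day 8, 270 for GSK343 at day 4, 2276 and 4902 for wild type from ES cells to day 4 and on to day 8, 1808 and 3227 for the mutant, 4928 and 740 for GSK343, and 10 and 2895 for the differences between GSK343 and DMSO. Where numbers pair, the block also moved the germline list of mutant day 4 from 0.0404 to 0.0529, the PRC2 subunit list of wild-type day 4 against ES cells from 0.0866 to 0.0416 and the feeder list of mutant day 8 against day 4 from 0.0401 to 0.0800, and changed no other list call. These camera adjusted p are at the preset correlation. With the estimated correlation 191 of 197 list calls of the main fits were lost. The numbers were not taken to pair mutant and wild type in ES cells (lowest r 0.0494) or at day 8 (-0.259), DMSO then GSK343 (-0.106) or GSK343 then DMSO (-0.203) with DMSO then DMSO, or the groups with 2 pairs (r 0.358 to 0.666 in the DMSO and GSK343 table and -0.481 to 0.515 for GSK343 then GSK343). As a hint from the data, 4 of 6 libraries of mutant and wild type correlated best with their own number in ES cells and 4 of 6 at day 8, and 0 of 6 and 3 of 6 in these replated comparisons.

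Leaving out 1 library at a time gave these lowest and highest counts: mutant against wild type 4 to 15 in ES cells, 4 to 97 at day 4 and 16 to 1308 at day 8, GSK343 against DMSO 0 to 16, 1 to 21 and 2732 to 3922, wild type 357 to 1707 from ES cells to day 4 and 828 to 4408 on to day 8, mutant 323 to 700 and 510 to 1497, DMSO 2133 to 3634 and 3639 to 4231, GSK343 1238 to 2393 and 1 to 1610. For the differences of change they were 0 to 1 and 0 to 29 in the mutant and 0 to 2 and 847 to 1914 under GSK343. For replated cells they were 0 to 595 for GSK343 then DMSO and 0 to 1410 for GSK343 then GSK343 against DMSO then DMSO, and 0 to 2124 for GSK343 then GSK343 against DMSO then GSK343. The camera p of PRC2 targets ran from 0.0410 to 0.868 in mutant ES cells, 0.0433 to 0.715 at mutant day 4, 0.0377 to 0.847 in GSK343 ES cells, 0.00989 to 0.150 at GSK343 day 8, 0.00341 to 0.379 for GSK343 then DMSO, 0.0127 to 0.269 for GSK343 then GSK343 against DMSO then DMSO and 0.0192 to 0.860 against GSK343 then DMSO. List medians that changed sign included those that ran from -0.46 to 0.10 for hypoxia in mutant ES cells, -0.10 to 1.48 for primitive streak at mutant day 4, -1.08 to 0.0594 for cell division in GSK343 then GSK343 against GSK343 then DMSO, and in the replated interaction from -0.23 to 1.18 for cell division, -1.26 to 0.44 for feeder and -0.53 to 0.14 for Hox. The median of p53 targets at GSK343 day 4 was -0.00850 without GSK343 day 4 library 1.

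With only the longer 50% of the peaks, overlap with H3K27me3 peaks was 98.7% for Ezh2, 93.9% for Ring1B and 100% for Suz12, of Ezh2 with Suz12 82.7% and of Suz12 with Ring1B 92.7%. For single Suz12 lists it was 3.32% in wild-type ES cells, 49.8% at wild-type day 8, 25.2% in mutant ES cell library 1, 10.4% in mutant day 4 library 2 and 37.5% in mutant day 8 library 2, and between mutant libraries 4.50% in ES cells and 6.74% at day 8. With 50% of the smaller peak shared, mutant libraries overlapped in 2.94% in ES cells, 1.06% at day 4 and 4.58% at day 8. For mutant lists at the wild-type list of their stage, that rule gave 2.07% and 5.15% in ES cell libraries 1 and 2, 0.184% in day 4 library 1 and 22.1% in day 8 library 2, and the longer 50% of peaks 5.16% in ES cell library 2 and 8.25% and 29.8% in day 8 libraries 1 and 2.

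Calls of named genes were kept in 2337 and lost in 645 leave-one-out fits. They were kept in 558 and lost in 20 with a pseudocount of 0.1, 520 and 8 with a filter at 2 RPKM, 574 and 4 with eBayes without the trend, 564 and 14 with centring, 577 and 1 with no filter, 436 and 142 with only the groups of the contrast, 492 and 84 with voom, 18 and 195 with no second libraries, and 578 and 0 with the block. List calls were kept in 6 and lost in 191 with the estimated correlation.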

Other observations

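The tests of loss of the Y chromosome, of EZH2 activity, of swapped labels and of feeder share were chosen only after the result was seen, and the other splits of the samples and the test of whole chromosomes were written before. Other splits of the same libraries were refitted for each count between groups of 3. For mutant against wild type, splits with at least as many calls were 2 of 10 in ES cells (13 genes, highest other 510), 2 of 10 at day 4 (7, highest other 197) and 2 of 10 at day 8 (214, highest other 2916), and 10 splits are too few for a share under 0.05. In each stage the highest split set wild-type libraries 1 and 2 and mutant library 1 against wild-type library 3 and mutant libraries 2 and 3. A split with many times the real count points to structure of the samples other than genotype, which the labels do not name. At day 4, where the numbers pair, the highest other split that parted each pair gave 0.

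For the differences of change between genotypes the real count was 0 in both steps. All splits reach 0, so 100 of 100 draws with at least as many say nothing, and the highest other was 714 from ES cells to day 4 and 2378 from day 4 to day 8. For steps in time the real split was the highest, 1 of 10 each, for wild type from ES cells to day 4 (1230, highest other 1) and from day 4 to day 8 (2942, highest other 13) and for the mutant (903 and 1466, highest other 0). For DMSO then GSK343 and GSK343 then DMSO against DMSO then DMSO the real count was also 0, with 0 the highest other, so 10 of 10 splits say nothing. For the steps in time 10 splits are too few for a share under 0.05.

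The Y-linked genes were lower in the mutant libraries at each stage. Loss of the Y chromosome in the mutant cells would leave nearly nothing of each, and at day 8 the mutant means were 0.205% of wild type for Ddx3y, 0.275% for Eif2s3y and 0.118% for Uty, the values that such a loss needs. Gain or loss of other whole chromosomes is argued against, since the largest chromosome median kept with 1 sign at the 3 stages was 0.0706 in size, for the X. Loss of EZH2 activity as the whole cause of the lower Y-linked genes is argued against by the inhibitor, since GSK343 gave -0.14 (SE 0.34) for Ddx3y, -0.23 (SE 0.19) for Eif2s3y and -0.33 (SE 0.36) for Uty at day 8, a median of -0.23 against -4.06 in the mutant. A small part of it, a fuller or longer loss of activity in the mutant than under GSK343, and other differences that a cloned line carries stay open and were not tested.

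Pluripotency genes were higher in replated libraries that started in GSK343 than in those of DMSO then GSK343. A swap of labels between a DMSO then GSK343 and a GSK343-started library is argued against, since 0 GSK343-started libraries lay in the range of DMSO then GSK343. The smallest log2 gap between them was 3.01. Exchanging DMSO then DMSO library 1 with a GSK343-started library could not narrow that gap, because library 1 itself lay in their range. That exchange therefore tests nothing, and exchanges of DMSO then DMSO libraries 2 and 3 were not run. A wrong label of DMSO then DMSO library 1 alone stays open and lies outside this pattern. A different share of feeder cells cannot be told apart from the treatment. The Y-linked genes of the male line changed by a median of 0.0625 between the GSK343-started groups and DMSO then GSK343, against a rise of 3.93 in the pluripotency list. But the lowest Xist value of replated libraries, 3.10 RPKM, lay below the highest of ES cells and embryoid bodies, 4.68 RPKM. These Xist values come from separate experiments, and the wild-type and mutant RPKM carry a further scaling, so their comparison is rough. A different share of cells that had left differentiation in each culture, as the spread of Pou5f1 in DMSO then DMSO would also allow, was not tested.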
